A study of Mus musculus with 6 samples.

How the data were processed

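The series compared kidneys of female C57BL/6 mice injected with folic acid with those of mice given vehicle, 3 arrays per group. Per the labels' protocols, total RNA was extracted with Trizol and labelled with biotin by the GeneChip WT PLUS kit, while the labels name poly-A RNA as the molecule. The array model, the library files and the genome build are not given in the sources used here, so no coordinates are printed. The authors deposited log2 values of each transcript cluster (the array's unit for a gene) on each of the 6 arrays. RMA, which corrects background, normalizes by quantiles and summarises probes, and Affymetrix Expression Console are named in the submitters' processing notes, without versions. The same log2 values stood in both deposited tables (largest difference 0). One of them also held the authors' ratio of AKI over control and the authors' p-values and adjusted p-values, with 1 p-value cell blank. In all 28361 rows the deposited ratio equalled the mean of the unlogged AKI values over the mean of the unlogged control values, with a tolerance of 1e-9.

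Of the 28361 transcript clusters, 25465 named 1 gene, 2894 none and 2 several. Gene symbols were updated through the RefSeq gene table of the mouse, matching 22115 clusters by accession, 1815 by symbol and 625 by a unique synonym, and 910 kept the deposited name. Where a gene had several clusters (1845 genes), the one with the highest mean over all 6 arrays was used, which left 22061 genes. No filter on dim clusters was set. The files hold no detection calls, so the signal over background is unknown and no gene is called absent. Folds of dim genes are compressed on arrays.

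The groups came from the labels (control and AKI). The 22061 genes were tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of adjusted p under 0.05. The moderated variance used 3.88 prior degrees of freedom. Each of 34 gene lists was tested against all other genes with camera at a preset correlation of 0.01, adjusted over the 34 lists. The preset called 22 lists, 14 up and 8 down, and 0 of them held with an estimated correlation. None of the lists was chosen on these samples. In the lists 16 genes stood in more than 1 list. Slc7a7, Fpr2, Hbb-bs, Hbb-b2, Tnfsf12 and Hspa1b were not matched to a cluster and were not analysed here. The design, the gene lists, the alternative settings and the rule for named genes were fixed before the data were examined. The rule took the 10 largest increases and 10 largest decreases past the test with separated groups, 10 genes named regardless of result, and up to 3 members per list in its main direction and 2 in the other, or the most displaced member where none passed. Members beyond the rule that moved against their list were named after their values were seen. Values of 2 genes that the rule named are not reported here.

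The procedure was tested on simulated data with the real gene means and with variances drawn at random from the fitted prior, equal in both groups. Some real genes varied far more in AKI, such as Egf (SD 1.51 against 0.05 in control), so the rates below may not hold for them. It recovered 38.8% of 67 genes changed 1.5-fold, 79.1% of 67 changed 2-fold and 98.5% of 66 changed 4-fold. Far fewer genes were changed there than were called in the real arrays (3241). The adjustment is stricter when few genes change, so these recovery rates do not carry over to the real comparison. Of 155 genes called, 11 (7.1%) were unchanged, 0 had the wrong sign, and 0 genes were called when none was changed. Of the lists, camera called 0 when none was shifted. With the proximal tubule list shifted by 0.5 it called 2, that list and the klotho, vitamin D and phosphate list, which shares 4 genes with it. Simulated genes varied independently, so the correlation within lists was not tested. Alternatives were 3 further normalizations, filters at the 25th percentile and the median of gene means, averaging of clusters, all rows, eBayes with trend and robust settings, array weights, the replicate number as a block, each array left out, a threshold of 0.01, treat against a 1.5-fold change, the authors' deposited table and, for lists, camera with an estimated correlation, fry and camera on ranks. Counts of list members without each array were added after seeing the data. Intervals of medians came from 2000 bootstrap draws of genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.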

Results

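Gene expression was measured in the kidneys of 12-week-old female C57BL/6 mice, with 1 Affymetrix array for each of 6 samples. Folic acid, which injures the renal tubule when given in a large dose, was injected once into the peritoneum at a dose of 250 mg/kg, dissolved in sodium bicarbonate (0.3 mol/L). Control mice received the vehicle. Kidneys were taken at 24 h, and the labels give 3 mice per group without naming the animal behind each array, so n = 3 arrays per group throughout. The injected group is called AKI (acute kidney injury). Values were log2 intensities after RMA, with array medians of 6.07 to 6.13 and lower quartiles of 4.31 to 4.49. With no reads to count, the number of arrays limited the precision. The comparison of AKI with control addressed which genes changed in the injured kidney.

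Injury markers, inflammatory mediators and cell cycle genes rose in the AKI kidneys, and transporters of the tubule and enzymes of mitochondrial metabolism fell. Of the gene lists tested, 30 of 36 injury markers, 20 of 31 chemokines and cytokines and 22 of 26 cell cycle genes rose, and 25 of 37 proximal tubule genes, 18 of 28 fatty acid oxidation genes and 22 of 40 tricarboxylic acid cycle and respiratory chain genes fell. As lists, none of these passed with an estimated correlation (adjusted p = 0.246 to 0.264). Fgb, the beta chain of fibrinogen, showed the largest increase, 14.7-fold, and Hpd, a dioxygenase of tyrosine breakdown, the largest decrease, 10.9-fold. Without AKI replicate 1, Timp1 led the increases. The log2 difference of Hpd was -4.34 without AKI replicate 1 and -2.88 without AKI replicate 3, where Car3 led the decreases (-3.84). The call of Hpd was lost without control replicates 1 and 3 and without AKI replicate 2, where Tmem207 led the decreases past the test. Of 22061 genes tested, 3241 (14.7%) differed between the groups at adjusted p under 0.05 (limma, Benjamini-Hochberg). Of these, 1509 were higher and 1732 lower in AKI, and 598 differed at least 2-fold, 250 of them higher and 348 lower. In all 3241 genes the 3 AKI values lay on one side of the 3 control values. Such separation was seen for 32.5% of all genes tested, against 10% by chance. Differences below are in log2 units, AKI minus control, ± the standard error of the limma fit.

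AKI replicate 1 lay nearer the controls than the other AKI arrays. Across genes, which are not independent replicates, its Pearson correlation with the 3 control arrays was 0.987 to 0.989, against 0.972 to 0.979 for AKI replicates 2 and 3. Among the 250 genes that rose at least 2-fold, the median change from the control mean was 0.93 on AKI replicate 1, 1.40 on AKI replicate 2 and 1.59 on AKI replicate 3. The 348 genes that fell at least 2-fold had medians of -0.83, -1.53 and -1.66 on the same arrays. The count of differing genes was 5364 without AKI replicate 1, 590 without AKI replicate 2 and 2197 without AKI replicate 3. It was 1132, 1316 and 1160 without control replicates 1, 2 and 3. Where a list's count is given without single arrays below, the order is control replicates 1, 2 and 3, then AKI replicates 1, 2 and 3.

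**Figure D1:**
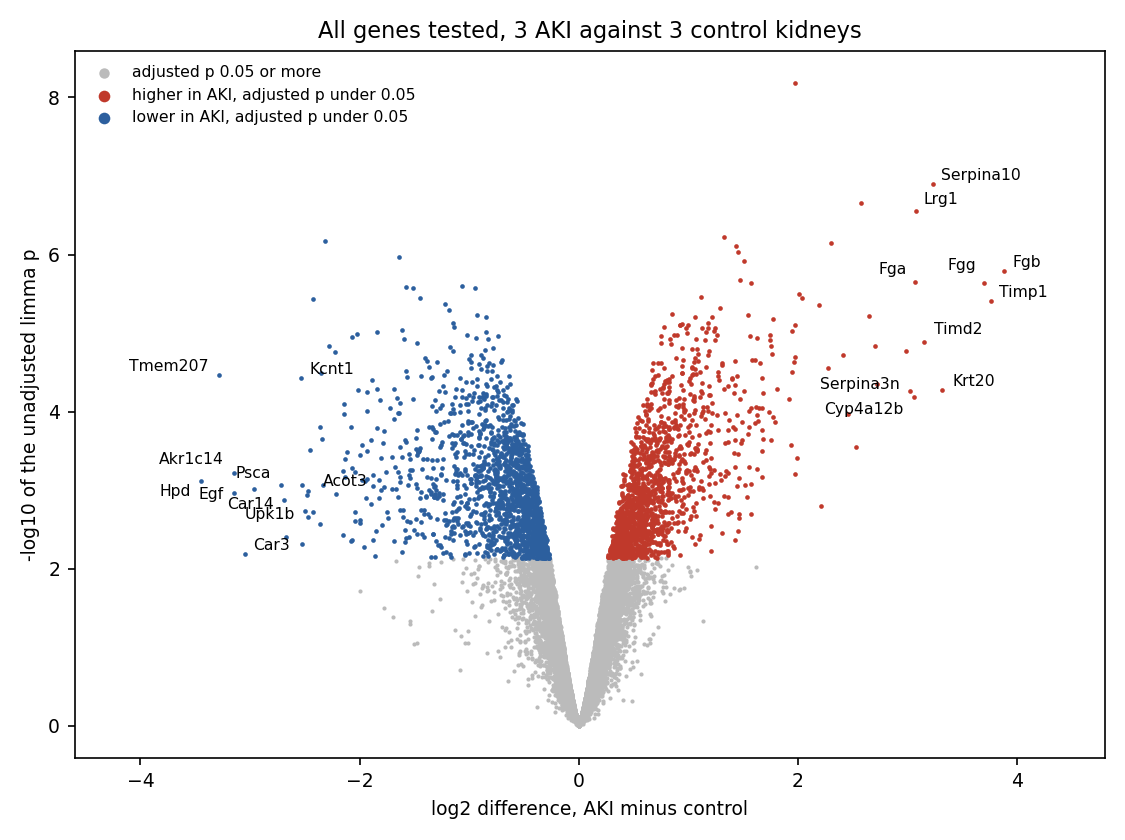
Each point is 1 of the 22061 genes tested, placed by its log2 difference between 3 AKI and 3 control arrays (horizontal axis) and by -log10 of its unadjusted limma p (vertical axis). Red points (1509) were higher and blue points (1732) lower in AKI at adjusted p under 0.05, and the 10 largest increases and decreases of the named genes carry labels.

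All 3 fibrinogen chains were among the 10 genes that rose most. Besides Fgb (3.88 ± 0.31, adjusted p = 0.00297), Fgg rose by 3.70 ± 0.31 (adjusted p = 0.00297) and Fga by 3.07 ± 0.25 (adjusted p = 0.00297). Timp1, an inhibitor of matrix metalloproteinases, rose by 3.76 ± 0.33, from 6.16 ± 0.48 (SD) in control to 9.92 ± 0.63 (SD) in AKI (adjusted p = 0.00335). The keratin Krt20 rose 9.95-fold (adjusted p = 0.00541). Serpina10, an inhibitor of coagulation proteases, rose 9.40-fold (adjusted p = 0.00139), and Serpina3n, an acute-phase protease inhibitor, 8.15-fold (adjusted p = 0.00541). Lrg1, a secreted leucine-rich glycoprotein of the acute phase, rose 8.42-fold (adjusted p = 0.00152), and Timd2, a cell-surface receptor, 8.87-fold (adjusted p = 0.00369). Cyp4a12b, an omega-hydroxylase of fatty acids that is more abundant in male than in female mouse kidney, rose by 3.06 ± 0.40 (adjusted p = 0.00562). Its near-identical neighbour Cyp4a12a, chosen after its values were seen, rose by 2.73 ± 0.34 (adjusted p = 0.00513), and the array values of this pair cannot be assigned to one or the other gene with certainty. All 10 genes stayed past the test when any 1 of the 6 arrays was left out.

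The 10 genes that fell most included enzymes and transport proteins of the tubule and markers of the urothelium. Hpd fell (-3.45 ± 0.65, adjusted p = 0.0143), and Egf, the epidermal growth factor made in the distal tubule, fell from 11.79 ± 0.05 (SD) to 8.65 ± 1.51 (SD; adjusted p = 0.0169). Akr1c14, a hydroxysteroid dehydrogenase, fell 8.86-fold (adjusted p = 0.0129) and Tmem207 9.76-fold (adjusted p = 0.00482). Car14, a membrane-bound carbonic anhydrase, fell 6.44-fold (adjusted p = 0.0188). The sodium-activated potassium channel gene Kcnt1 fell 5.79-fold (adjusted p = 0.00489) and the acyl-CoA thioesterase gene Acot3 5.59-fold (adjusted p = 0.0175). Car3, a carbonic anhydrase abundant in fat and muscle, fell (-3.05 ± 0.83, adjusted p = 0.0465). Psca, a surface antigen of the urothelium, fell (-2.72 ± 0.52, adjusted p = 0.0151), as did the uroplakin gene Upk1b (-2.50 ± 0.54, adjusted p = 0.0227). In the same arrays 10 other fat markers had a median log2 difference of -0.82, and 9 urothelial markers other than Psca, Upk1a and Upk1b one of -0.47. Upk1a, chosen after its values were seen, fell 5.08-fold (limma adjusted p = 0.00882). Of the 10 genes, 2 stayed past the test without AKI replicate 2 (Tmem207 and Kcnt1), and 3, 5 and 4 without control replicates 1, 2 and 3. Without AKI replicate 1, Car3 alone was lost. Car3 was lost without AKI replicate 2 and without each control replicate too. Its call was also lost with the robust eBayes, with the replicate block and in the authors' deposited table.

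**Figure D2:**
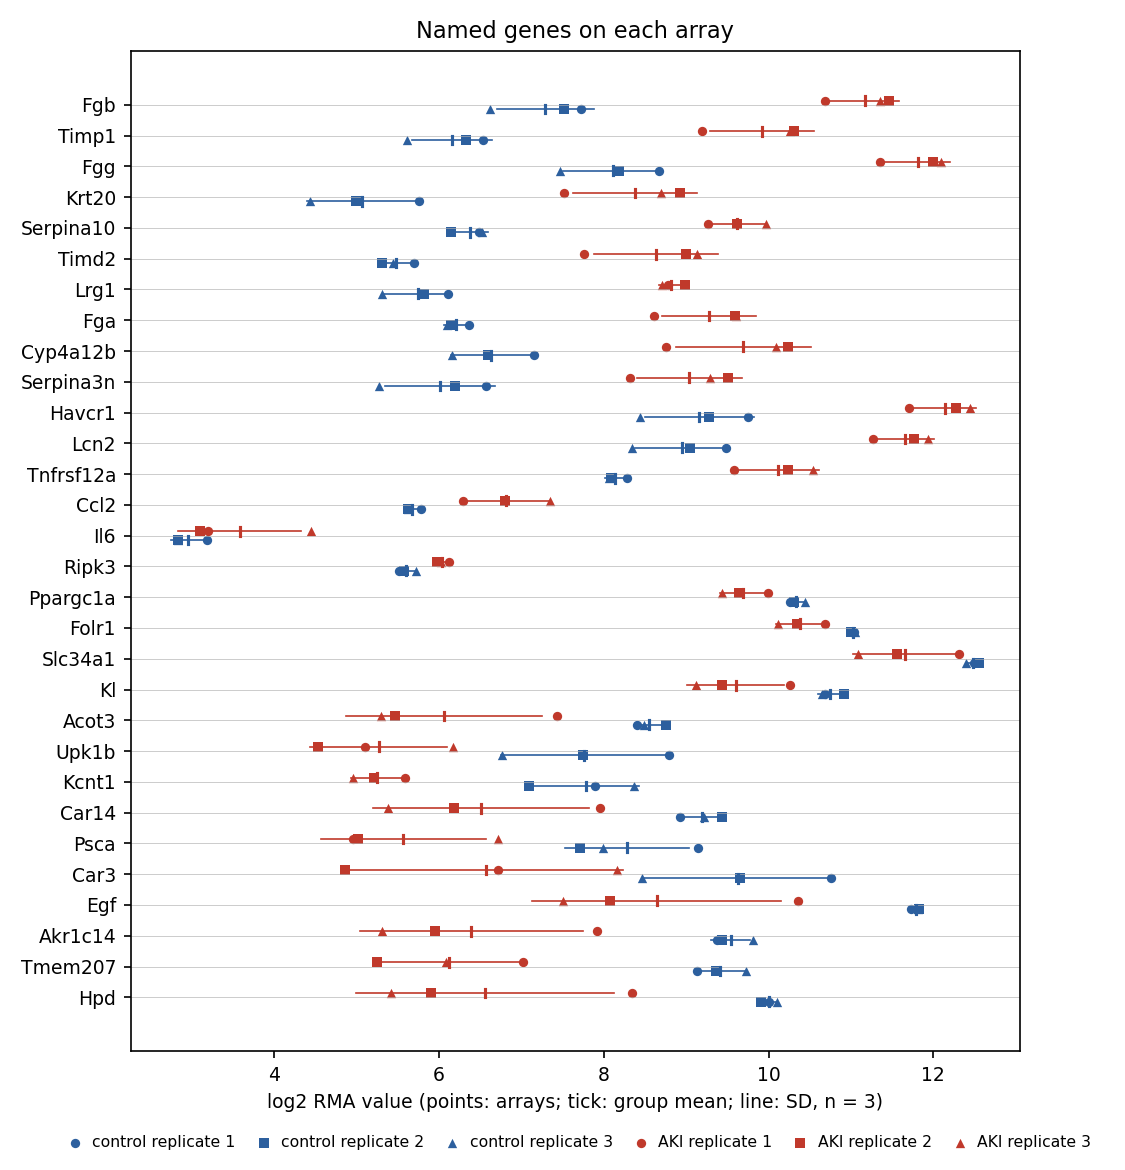
Points are the log2 values of the 10 largest increases, the 10 largest decreases and the 10 genes named regardless of result, on each of the 6 arrays (blue control, red AKI; circle, square and triangle for replicates 1, 2 and 3), with each group's mean (tick) and SD (line, n = 3). Fgb rose from a control mean of 7.29 to 11.17 in AKI.

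Markers of the injured tubule rose together. Of the 36 measured, 30 rose, 0 fell and 6 did not pass the test, or 30 rose and 0 fell adjusted over the list alone, with a median difference of 1.39 (camera adjusted p = 1.73e-22, adjusted p = 0.255 with an estimated correlation). Havcr1, which encodes KIM-1 and is induced in the damaged proximal tubule, rose 7.90-fold, from 9.16 ± 0.66 (SD) to 12.14 ± 0.38 (SD; adjusted p = 0.00403). Lcn2, the gene of the iron-siderophore carrier NGAL, rose 6.51-fold (adjusted p = 0.00388). The fibrinogen genes, Timp1, Krt20, Lrg1 and Serpina10 described above belong to this list. The mean of the list lay 1.20 above the control mean on AKI replicate 1, 1.77 on AKI replicate 2 and 1.96 on AKI replicate 3. Of the 30 genes that rose, 16 stayed past the test without AKI replicate 2, and 27, 23 and 22 without control replicates 1, 2 and 3.

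Genes that carry out transport in the proximal tubule fell. Among 37 transporters and receptors, 1 rose, 25 fell and 11 did not pass the test, or 1 rose and 31 fell adjusted over the list alone, with a median difference of -0.83 (camera adjusted p = 7.09e-13, adjusted p = 0.264 with an estimated correlation). Slc22a30, a member of the organic anion transporter family, fell (-2.07 ± 0.37, adjusted p = 0.0120), as did the amino acid transporter gene Slc6a20b (-1.60 ± 0.35, adjusted p = 0.0221) and the phosphate transporter gene Slc34a3 (-1.59 ± 0.41, adjusted p = 0.0377). Slc13a1, the sodium-sulfate cotransporter of the brush border, moved against the list and rose by 0.85 ± 0.08 (adjusted p = 0.00355). Slc34a1, the main phosphate transporter gene of the proximal tubule, did not pass the test at -0.83 ± 0.27 (adjusted p = 0.0802). The list's mean lay 0.35 below the control mean on AKI replicate 1, 0.96 below on AKI replicate 2 and 1.12 below on AKI replicate 3. Slc34a3 lost the call in 5 of the 6 fits with 1 array left out and Slc6a20b in 4.

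Markers of distal segments fell as well, though not all. In the loop of Henle and distal tubule, of 22 markers 1 rose, 14 fell and 7 did not pass the test, or 1 rose and 17 fell adjusted over the list alone, with a median difference of -0.80 (camera adjusted p = 6.18e-10, adjusted p = 0.264 with an estimated correlation). Besides Egf, Slc12a1, the sodium-potassium-chloride cotransporter of the thick ascending limb, fell (-2.15 ± 0.30, adjusted p = 0.00647), as did the gene of the calcium-binding protein Pvalb (-1.68 ± 0.30, adjusted p = 0.0119). Trpv5, the apical calcium channel of the distal tubule, rose by 1.19 ± 0.23 (adjusted p = 0.0150). Of 18 collecting duct markers, 0 rose, 8 fell and 10 did not pass the test, or 0 rose and 12 fell adjusted over the list alone, with a median difference of -0.73 (camera adjusted p = 1.48e-07, adjusted p = 0.246 with an estimated correlation). The water channel genes Aqp4 and Aqp3 fell (-2.04 ± 0.45 and -1.01 ± 0.16, adjusted p = 0.0230 and 0.00846). Slc4a1, the basolateral anion exchanger of acid-secreting cells, fell (-1.84 ± 0.23, adjusted p = 0.00537). Trpv5 lost the call in 3 of the 6 fits with 1 array left out, Aqp4 in 2, and Pvalb in 1.

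Some of the transcription factors that maintain these segments changed too. Of 18, 1 rose, 4 fell and 13 did not pass the test, or 1 rose and 6 fell adjusted over the list alone, with a median difference of -0.38 (camera adjusted p = 2.31e-05, adjusted p = 0.264 with an estimated correlation). The estrogen-related receptor gene Esrrb fell (-1.34 ± 0.21, adjusted p = 0.00882), as did the mineralocorticoid receptor gene Nr3c2 (-0.63 ± 0.11, adjusted p = 0.0110) and Tfap2b (-0.61 ± 0.10, adjusted p = 0.0107). Pax8, a factor of kidney development, rose by 0.55 ± 0.15 (adjusted p = 0.0476). The call of Pax8 was lost under median centring, with the replicate block and in the authors' deposited table, which adjusted the same test over all rows. For the klotho, vitamin D and phosphate axis, of 11 genes 0 rose, 5 fell and 6 did not pass the test, or 3 rose and 6 fell adjusted over the list alone, and the list as a whole did not pass (median difference -0.60, camera adjusted p = 0.103, adjusted p = 0.388 with an estimated correlation). Kl, the gene of the FGF23 coreceptor klotho, fell 2.21-fold, from 10.75 ± 0.15 (SD) to 9.60 ± 0.59 (SD; adjusted p = 0.0260), as did the endocytic receptor gene Cubn (-0.94 ± 0.18, adjusted p = 0.0146). The axis list passed without control replicate 3 (adjusted p = 0.0234) and without AKI replicate 1 (adjusted p = 0.0241). Without single arrays, the fallen genes numbered 4, 4, 3, 32, 2 and 11 for the proximal tubule. They numbered 9, 9, 9, 16, 6 and 11 for the loop and distal tubule and 3, 5, 2, 9, 3 and 6 for the collecting duct. Counts were 4, 4, 4, 10, 1 and 4 for the transcription factors, with 0, 0, 0, 1, 0 and 0 risen. They were 0, 0, 0, 6, 0 and 2 for the klotho, vitamin D and phosphate axis. Pax8 and Kl lost the call in 5 of the 6 fits with 1 array left out, Cubn in 4, and Nr3c2 and Tfap2b in 1.

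Enzymes of mitochondrial energy supply fell. Of 28 fatty acid oxidation genes, 0 rose, 18 fell and 10 did not pass the test, or 1 rose and 24 fell adjusted over the list alone, with a median difference of -0.45 (camera adjusted p = 2.00e-12, adjusted p = 0.264 with an estimated correlation). The peroxisomal enzyme gene Ehhadh fell (-1.48 ± 0.24, adjusted p = 0.00964), as did the acyl-CoA synthetase gene Acsl1 (-1.17 ± 0.16, adjusted p = 0.00646). Ppargc1a, a coactivator of mitochondrial biogenesis, fell 1.56-fold, from 10.33 ± 0.09 (SD) to 9.69 ± 0.28 (SD; adjusted p = 0.0243). In the tricarboxylic acid cycle and respiratory chain, of 40 genes 0 rose, 22 fell and 18 did not pass the test, or 0 rose and 34 fell adjusted over the list alone, with a median difference of -0.37 (camera adjusted p = 5.08e-17, adjusted p = 0.264 with an estimated correlation). Decreases there were small, with the complex I genes Ndufs1 at -0.64 ± 0.10 and Ndufb5 at -0.56 ± 0.09 and the complex III gene Uqcrfs1 at -0.56 ± 0.10 among the largest (adjusted p = 0.00890, 0.00911 and 0.0133). Ppargc1a lost the call in 4 of the 6 fits with 1 array left out, Uqcrfs1 in 3, and Ehhadh, Ndufs1 and Ndufb5 in 1.

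Gluconeogenesis genes fell as a list, and no shift of glycolysis genes was detected. Of 8 gluconeogenesis genes, 0 rose, 6 fell and 2 did not pass the test, or 0 rose and 7 fell adjusted over the list alone, with a median difference of -1.08 (camera adjusted p = 6.02e-05, adjusted p = 0.303 with an estimated correlation). Pck1, the cytosolic PEP carboxykinase, fell (-1.86 ± 0.51, adjusted p = 0.0485), as did Fbp1 (-1.35 ± 0.27, adjusted p = 0.0168) and the glucose phosphate translocase gene Slc37a4 (-1.21 ± 0.28, adjusted p = 0.0282). The call of Pck1 was lost under quantile and cyclic loess normalization, with the robust eBayes and in the authors' deposited table, which adjusted the same test over all rows. Of 18 glycolysis genes, 1 rose, 1 fell and 16 did not pass the test, or 1 rose and 1 fell adjusted over the list alone (median difference 0.0045, camera adjusted p = 0.956, adjusted p = 0.977 with an estimated correlation), and the sign of that median turned under median centring (-0.0086). Hk2, a hexokinase, rose by 0.73 ± 0.12 (adjusted p = 0.0108), and the muscle-type phosphofructokinase gene Pfkm fell (-0.69 ± 0.13, adjusted p = 0.0140). Pck1 lost the call in 5 of the 6 fits with 1 array left out, Fbp1 and Slc37a4 in 4, and Pfkm in 3.

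Genes of folate and one-carbon metabolism, the pathways that handle the injected compound, changed in both directions. Of 26 genes, 4 rose, 9 fell and 13 did not pass the test, or 5 rose and 11 fell adjusted over the list alone, and the list as a whole did not pass (median difference -0.091, camera adjusted p = 0.119, adjusted p = 0.264 with an estimated correlation). Bhmt, which remethylates homocysteine with betaine, fell (-1.46 ± 0.24, adjusted p = 0.00984), as did Amt of the glycine cleavage system (-1.06 ± 0.16, adjusted p = 0.00864) and the cytosolic serine hydroxymethyltransferase gene Shmt1 (-0.68 ± 0.14, adjusted p = 0.0182). The folate receptor gene Folr1 fell 1.57-fold, from 11.03 ± 0.02 (SD) to 10.38 ± 0.29 (SD; adjusted p = 0.0216). The mitochondrial enzyme genes Mthfd2 (1.75 ± 0.28, adjusted p = 0.00890), Aldh1l2 (0.89 ± 0.15, adjusted p = 0.00971) and Mthfd1l (0.78 ± 0.10, adjusted p = 0.00513) rose, as did Atic (0.58 ± 0.16, adjusted p = 0.0449), an enzyme of purine synthesis. Atic lost the call in 5 of the 6 fits with 1 array left out, Folr1 in 4, Shmt1 in 3, and Bhmt, Amt, Mthfd2 and Aldh1l2 in 1.

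Cholesterol synthesis was mixed. Of 18 genes, 4 rose, 3 fell and 11 did not pass the test, or 4 rose and 3 fell adjusted over the list alone, and the list as a whole did not pass (median difference 0.11, camera adjusted p = 0.607, adjusted p = 0.801 with an estimated correlation). Msmo1, Fdps and Sqle rose by 0.82 ± 0.22, 0.79 ± 0.12 and 0.77 ± 0.18 (adjusted p = 0.0462, 0.00878 and 0.0297). Cyp51, the lanosterol demethylase, fell (-1.57 ± 0.13, adjusted p = 0.00297), as did Hmgcs1 (-0.33 ± 0.09, adjusted p = 0.0408). Fallen genes, without single arrays, numbered 6, 5, 6, 23, 3 and 10 in fatty acid oxidation. Those of the tricarboxylic acid cycle and respiratory chain numbered 6, 5, 5, 29, 1 and 13 and those of gluconeogenesis 1, 0, 1, 7, 0 and 4. Folate genes that rose numbered 3, 3, 3, 6, 1 and 3 and those that fell 3, 3, 4, 11, 0 and 8. Glycolysis genes that rose numbered 1, 1, 1, 4, 1 and 1 and those that fell 0, 0, 1, 1, 0 and 1. For cholesterol synthesis the counts were 2, 2, 3, 5, 1 and 2 risen and 2, 2, 2, 4, 2 and 2 fallen. Msmo1 and Hmgcs1 lost the call in 5 of the 6 fits with 1 array left out and Sqle in 4.

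Chemokines and cytokines rose in the AKI kidneys. Of 31 measured, 20 rose, 0 fell and 11 did not pass the test, or 20 rose and 0 fell adjusted over the list alone, with a median difference of 0.72 (camera adjusted p = 1.26e-12, adjusted p = 0.246 with an estimated correlation). Cxcl10, an interferon-inducible chemokine for T cells, rose by 2.20 ± 0.20 (adjusted p = 0.00346), the neutrophil-attracting chemokine gene Cxcl2 by 1.56 ± 0.28 (adjusted p = 0.0119) and Lif, a cytokine of the interleukin-6 family, by 1.54 ± 0.14 (adjusted p = 0.00355). Ccl2, the monocyte-attracting chemokine, rose 2.19-fold, from 5.68 ± 0.09 (SD) to 6.81 ± 0.53 (SD; adjusted p = 0.0182). Il6 did not pass the test, at 2.96 ± 0.20 (SD) in control and 3.58 ± 0.75 (SD) in AKI (adjusted p = 0.272), with group means below the lower quartile of each array and AKI replicate 3 highest at 4.45. Among 21 genes of the NF-kB pathway and its targets, 14 rose, 0 fell and 7 did not pass the test, or 15 rose and 0 fell adjusted over the list alone, with a median difference of 0.60 (camera adjusted p = 1.03e-11, adjusted p = 0.246 with an estimated correlation). Bcl3 and Nfkbiz, nuclear modulators of NF-kB, rose by 1.63 ± 0.17 and 1.32 ± 0.17 (adjusted p = 0.00355 and 0.00537), and the adhesion molecule gene Vcam1 by 1.26 ± 0.13 (adjusted p = 0.00355). Ccl2 lost the call in 4 of the 6 fits with 1 array left out and Cxcl2 in 1.

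Some interferon-stimulated and complement genes rose, and others fell. Of 20 interferon-stimulated genes, 8 rose, 3 fell and 9 did not pass the test, or 12 rose and 3 fell adjusted over the list alone, with a median difference of 0.39 (camera adjusted p = 2.25e-04, adjusted p = 0.303 with an estimated correlation). Gbp2, Zbp1 and Oasl2 rose by 0.91 ± 0.14, 0.79 ± 0.13 and 0.60 ± 0.10 (adjusted p = 0.00864, 0.00995 and 0.00949). Rsad2, which encodes the antiviral protein viperin, fell (-0.61 ± 0.12, adjusted p = 0.0159), as did Ifi44 (-0.44 ± 0.11, adjusted p = 0.0407) and Cmpk2 (-0.38 ± 0.10, adjusted p = 0.0469). Of 21 complement genes, 10 rose, 4 fell and 7 did not pass the test, or 11 rose and 4 fell adjusted over the list alone, with a median difference of 0.36 (camera adjusted p = 0.00118, adjusted p = 0.264 with an estimated correlation). C3, the central component of the cascade, rose by 2.31 ± 0.16 (adjusted p = 0.00214), its regulator Cfi by 1.97 ± 0.08 (adjusted p = 1.44e-04) and the C5a receptor gene C5ar1 by 1.74 ± 0.18 (adjusted p = 0.00355). The terminal component gene C8a fell (-1.65 ± 0.23, adjusted p = 0.00646), as did Cd59a, an inhibitor of the membrane attack complex (-0.94 ± 0.10, adjusted p = 0.00355). Cd55 (-0.76 ± 0.14, adjusted p = 0.0142) and Serping1 (-0.63 ± 0.17, adjusted p = 0.0426), which restrain complement activation, fell too. Risen genes, without single arrays, numbered 11, 14, 14, 20, 10 and 17 among chemokines and cytokines and 9, 8, 9, 14, 7 and 10 in the NF-kB list. Interferon-stimulated genes that rose numbered 4, 5, 4, 14, 1 and 5 and those that fell 0, 0, 0, 1, 0 and 3. Complement genes that rose numbered 6, 10, 6, 10, 5 and 7 and those that fell 2, 2, 4, 4, 2 and 3. Ifi44 and Cmpk2 lost the call in 5 of the 6 fits with 1 array left out, Rsad2 and Serping1 in 4, Cd55 in 3, and Gbp2, Zbp1 and Oasl2 in 1.

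Among immune cell markers, those of monocytes and macrophages rose. Of 20, 12 rose, 1 fell and 7 did not pass the test, or 13 rose and 1 fell adjusted over the list alone, with a median difference of 0.72 (camera adjusted p = 7.54e-08, adjusted p = 0.264 with an estimated correlation). Plac8 rose by 2.04 ± 0.18 (adjusted p = 0.00324), the lipopolysaccharide coreceptor gene Cd14 by 1.92 ± 0.25 (adjusted p = 0.00569) and the integrin gene Itgam by 1.77 ± 0.25 (adjusted p = 0.00690). Csf1r, the receptor for macrophage colony-stimulating factor, fell (-0.52 ± 0.11, adjusted p = 0.0223). No marker of the other leukocytes passed the test in limma. Of 16 neutrophil markers, 0 rose, 0 fell and 16 did not pass the test, or 0 rose and 0 fell adjusted over the list alone (median difference 0.022, camera adjusted p = 0.529, adjusted p = 0.811 with an estimated correlation), with Csf3r at 0.32 ± 0.12 the most displaced (adjusted p = 0.112). Of 17 T and NK cell markers, 0 rose, 0 fell and 17 did not pass the test, or 0 rose and 0 fell adjusted over the list alone (median difference 0.053, camera adjusted p = 0.399, adjusted p = 0.789 with an estimated correlation), with Lck at 0.36 ± 0.11 (adjusted p = 0.0782). Of 11 B cell markers, 0 rose, 0 fell and 11 did not pass the test, or 0 rose and 0 fell adjusted over the list alone (median difference -0.086, camera adjusted p = 0.183, adjusted p = 0.303 with an estimated correlation), with Cr2 at -0.42 ± 0.12 (adjusted p = 0.0544). Unadjusted p was under 0.05 for 1 neutrophil, 3 T and NK cell and 1 B cell markers. Csf1r lost the call in 5 of the 6 fits with 1 array left out.

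Some matrix genes rose, and the endothelial list was lower in AKI. Of 21 fibroblast and extracellular matrix genes, 9 rose, 2 fell and 10 did not pass the test, or 13 rose and 3 fell adjusted over the list alone, with a median difference of 0.54 (camera adjusted p = 2.22e-04, adjusted p = 0.303 with an estimated correlation). Ccn1, a matricellular protein, rose by 1.67 ± 0.27 (adjusted p = 0.00984), and the fibrillar collagen genes Col1a1 and Col3a1 by 1.56 ± 0.22 and 1.51 ± 0.19 (adjusted p = 0.00635 and 0.00541). The proteoglycan gene Dcn and the growth factor receptor gene Pdgfra fell (-0.76 ± 0.17 and -0.43 ± 0.08, adjusted p = 0.0228 and 0.0154). Of 17 endothelial markers, 0 rose, 5 fell and 12 did not pass the test, or 0 rose and 8 fell adjusted over the list alone, with a median difference of -0.28 (camera adjusted p = 8.04e-05, adjusted p = 0.246 with an estimated correlation). Kdr, the main VEGF receptor, fell (-0.54 ± 0.11, adjusted p = 0.0175), as did the sialomucin gene Emcn (-0.45 ± 0.09, adjusted p = 0.0169) and the transcription factor gene Erg (-0.39 ± 0.10, adjusted p = 0.0432). Dcn, Pdgfra, Kdr and Erg lost the call in 4 of the 6 fits with 1 array left out and Emcn in 3.

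Of 16 podocyte markers, 0 rose, 1 fell and 15 did not pass the test, or 0 rose and 1 fell adjusted over the list alone (median difference -0.073, camera adjusted p = 0.315, adjusted p = 0.789 with an estimated correlation), Clic5 being the one that fell (-0.68 ± 0.12, adjusted p = 0.0106). Of 15 perirenal fat and adrenal markers, 0 rose, 0 fell and 15 did not pass the test, or 0 rose and 0 fell adjusted over the list alone (median difference -0.14, camera adjusted p = 0.133, adjusted p = 0.303 with an estimated correlation), with the adipokine gene Retn at -1.78 ± 0.68 (adjusted p = 0.133). That list joins fat and adrenal genes, with quartiles of -1.05 and 0.033, so its median does not describe fat alone. Of 9 erythroid and blood markers, 1 rose, 0 fell and 8 did not pass the test, or 1 rose and 0 fell adjusted over the list alone (median difference -0.68, camera adjusted p = 0.188, adjusted p = 0.672 with an estimated correlation), Epb42, a red cell membrane protein, being the one that rose (0.53 ± 0.11, adjusted p = 0.0196). The podocyte and fat lists passed without control replicate 3 (adjusted p = 0.0204 and 0.0206), and the erythroid list without control replicate 2 (adjusted p = 0.00807). Risen markers of monocytes and macrophages numbered 8, 10, 9, 14, 6 and 10 without single arrays, and fallen ones 0, 0, 0, 1, 0 and 0. Risen matrix genes numbered 5, 8, 7, 13, 4 and 8 and those that fell 0, 0, 2, 2, 0 and 1. Fallen endothelial markers numbered 0, 1, 0, 7, 0 and 7 and fallen podocyte markers 1, 1, 2, 1, 0 and 2. Risen erythroid markers numbered 0, 0, 0, 1, 0 and 1. Epb42 lost the call in 4 of the 6 fits with 1 array left out and Clic5 in 1.

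**Figure D3:**
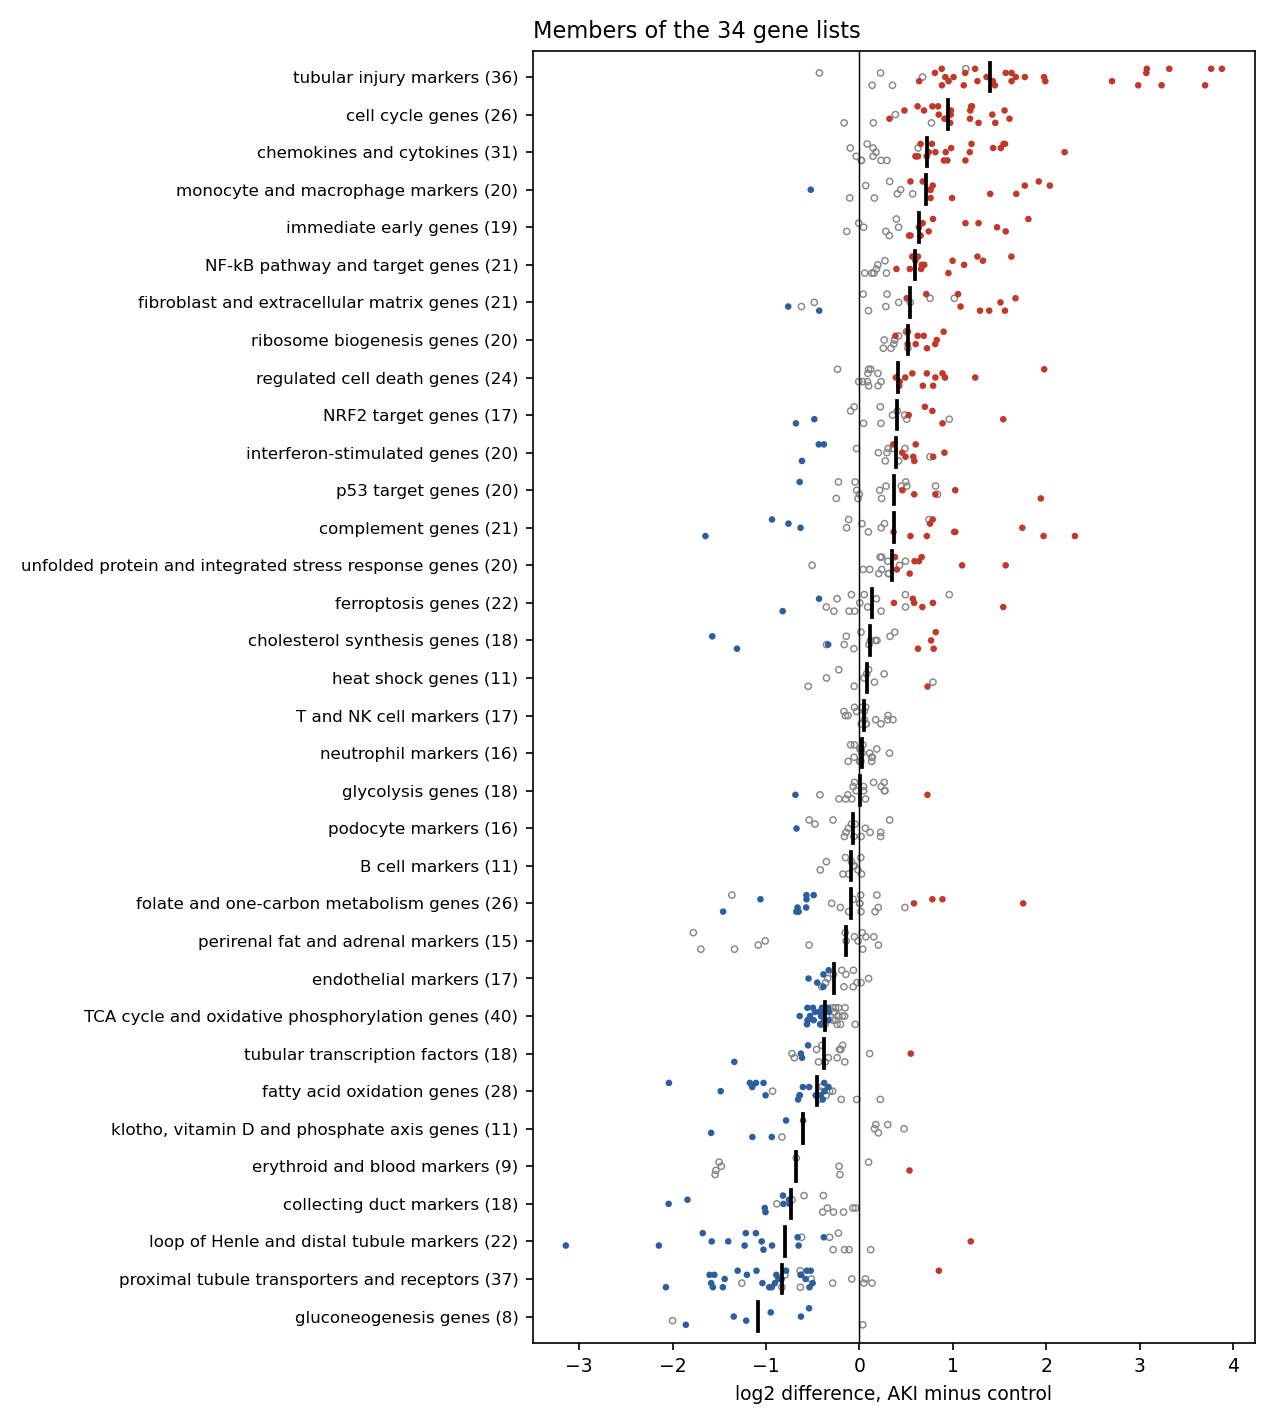
Each point is a measured member of 1 of the 34 gene lists (list size in brackets), placed by its log2 difference, AKI minus control, with n = 3 arrays per group; the black bar is the list median. Filled points passed the test (red higher, blue lower in AKI), open points did not; medians run from 1.39 for tubular injury markers to -1.08 for gluconeogenesis genes.

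Genes of regulated cell death rose. Of 24, 13 rose, 0 fell and 11 did not pass the test, or 13 rose and 0 fell adjusted over the list alone, with a median difference of 0.41 (camera adjusted p = 2.52e-07, adjusted p = 0.246 with an estimated correlation). Tnfrsf12a, which encodes the TWEAK receptor Fn14, rose 3.93-fold, from 8.14 ± 0.12 (SD) to 10.12 ± 0.49 (SD; adjusted p = 0.00431). Mlkl, the executor of necroptosis, rose by 1.24 ± 0.22 (adjusted p = 0.0125), its kinase Ripk3 by 0.43 ± 0.09 (adjusted p = 0.0197) and the TNF receptor gene Tnfrsf1a by 0.92 ± 0.12 (adjusted p = 0.00566). Of 22 ferroptosis genes, 6 rose, 2 fell and 14 did not pass the test, or 10 rose and 3 fell adjusted over the list alone, and the list as a whole did not pass (median difference 0.13, camera adjusted p = 0.147, adjusted p = 0.303 with an estimated correlation). Hmox1, the inducible heme oxygenase, rose by 1.54 ± 0.31 (adjusted p = 0.0182), Acsl4, which prepares polyunsaturated fatty acids for membranes, by 0.79 ± 0.17 (adjusted p = 0.0202) and the metal transporter gene Slc39a14 by 0.67 ± 0.13 (adjusted p = 0.0153). The ferrireductase gene Steap3 and the ferritin receptor gene Ncoa4 fell (-0.82 ± 0.13 and -0.43 ± 0.08, adjusted p = 0.00952 and 0.0140). Hmox1, Acsl4 and Ncoa4 lost the call in 4 of the 6 fits with 1 array left out, Mlkl, Ripk3 and Slc39a14 in 3, and Steap3 in 1.

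Some genes of the stress pathways rose. Of 17 NRF2 target genes, 5 rose, 2 fell and 10 did not pass the test, or 9 rose and 2 fell adjusted over the list alone, with a median difference of 0.40 (camera adjusted p = 0.0108, adjusted p = 0.445 with an estimated correlation). Besides Hmox1, Srxn1 and G6pdx rose by 0.89 ± 0.18 and 0.78 ± 0.17 (adjusted p = 0.0189 and 0.0228), while Osgin1 and the malic enzyme gene Me1 fell (-0.68 ± 0.16 and -0.48 ± 0.08, adjusted p = 0.0275 and 0.0102). Of 20 p53 target genes, 5 rose, 1 fell and 14 did not pass the test, or 11 rose and 2 fell adjusted over the list alone, with a median difference of 0.37 (camera adjusted p = 0.00808, adjusted p = 0.479 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, rose by 1.94 ± 0.31 (adjusted p = 0.00928), Gadd45a by 1.02 ± 0.17 (adjusted p = 0.0101) and the apoptosis effector gene Bax by 0.81 ± 0.22 (adjusted p = 0.0442). The stress gene Sesn1 fell (-0.64 ± 0.08, adjusted p = 0.00482). Both list calls were lost without AKI replicate 3 (NRF2 adjusted p = 0.0827, p53 adjusted p = 0.0652) and among genes at or above the median level (adjusted p = 0.0743 and 0.0861). Fry, which tests a list against no change and not against other genes, did not call them (adjusted p = 0.180 and 0.182). Osgin1 and Bax lost the call in 5 of the 6 fits with 1 array left out, Srxn1 and G6pdx in 4, and Me1 and Cdkn1a in 1.

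Of 20 genes of the unfolded protein and integrated stress response, 8 rose, 0 fell and 12 did not pass the test, or 14 rose and 1 fell adjusted over the list alone, with a median difference of 0.35 (camera adjusted p = 2.89e-07, adjusted p = 0.264 with an estimated correlation). The stress-induced factors Atf3 and Atf5 rose by 1.56 ± 0.16 and 0.67 ± 0.10 (adjusted p = 0.00355 and 0.00886), and Asns, asparagine synthetase, by 1.10 ± 0.28 (adjusted p = 0.0360). Of 11 heat shock genes, 1 rose, 0 fell and 10 did not pass the test, or 1 rose and 0 fell adjusted over the list alone (median difference 0.077, camera adjusted p = 0.463, adjusted p = 0.801 with an estimated correlation), with the chaperone gene Hsp90aa1 rising by 0.73 ± 0.18 (adjusted p = 0.0327). Without single arrays, risen genes numbered 5, 6, 7, 14, 4 and 8 for regulated cell death. They numbered 1, 0, 0, 10, 0 and 2 for NRF2 targets and 3, 2, 2, 9, 1 and 3 for p53 targets. Counts were 0, 2, 1, 10, 0 and 4 for ferroptosis and 3, 3, 3, 13, 2 and 4 for the unfolded protein and integrated stress response. Risen heat shock genes numbered 1, 0, 0, 2, 0 and 0. Fallen NRF2 targets numbered 1, 1, 1, 2, 0 and 1 and fallen ferroptosis genes 1, 1, 1, 3, 0 and 2. Asns and Hsp90aa1 lost the call in 5 of the 6 fits with 1 array left out and Atf5 in 1.

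Genes of proliferation and growth rose. Of 26 cell cycle genes, 22 rose, 0 fell and 4 did not pass the test, or 24 rose and 0 fell adjusted over the list alone, with a median difference of 0.95 (camera adjusted p = 1.79e-15, adjusted p = 0.246 with an estimated correlation). Top2a, a topoisomerase of dividing cells, rose by 1.61 ± 0.23 (adjusted p = 0.00752), Rrm2, a subunit of ribonucleotide reductase, by 1.55 ± 0.23 (adjusted p = 0.00775) and the cyclin gene Ccna2 by 1.45 ± 0.24 (adjusted p = 0.0101). Of 20 ribosome biogenesis genes, 11 rose, 0 fell and 9 did not pass the test, or 17 rose and 0 fell adjusted over the list alone, with a median difference of 0.52 (camera adjusted p = 3.82e-09, adjusted p = 0.303 with an estimated correlation). The helicase gene Ddx21, the nucleolar methyltransferase gene Fbl and Nop58 rose by 0.90 ± 0.21, 0.83 ± 0.12 and 0.81 ± 0.22 (adjusted p = 0.0272, 0.00789 and 0.0477). Of 19 immediate early genes, 12 rose, 0 fell and 7 did not pass the test, or 16 rose and 0 fell adjusted over the list alone, with a median difference of 0.64 (camera adjusted p = 3.56e-09, adjusted p = 0.255 with an estimated correlation). Besides Atf3, Myc and Egr2 rose by 1.81 ± 0.23 and 1.47 ± 0.12 (adjusted p = 0.00537 and 0.00297). Mean changes of the cell cycle list were 0.64, 0.98 and 1.10 on AKI replicates 1, 2 and 3. Risen cell cycle genes numbered 15, 17, 14, 24, 8 and 19 without single arrays. The counts were 2, 2, 2, 20, 1 and 4 in the ribosome biogenesis list and 8, 7, 7, 14, 5 and 8 in the immediate early list. Ddx21 and Nop58 lost the call in 5 of the 6 fits with 1 array left out and Ccna2 in 1.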

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

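The counts over other splits of the 6 arrays, the count of clusters without a gene name and the ranks of arrays over fat and urothelial markers were tests chosen only after the results they bear on were seen.

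Among the 2896 transcript clusters that named no single gene and were outside the comparison of named genes, 104 differed between AKI and control (76 higher, 28 lower), 3.59% against 13.3% of the clusters that named 1 gene.

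AKI replicate 1 lay nearer the controls than AKI replicates 2 and 3. In 888 genes that differed at least 2-fold without that array (381 higher, 507 lower), it reached a median of 0.507 of the log2 change seen in AKI replicates 2 and 3. Control RNA mixed into the sample would give rising and falling genes the same share on the unlogged scale, but the medians were 0.445 and 0.600, a difference of -0.155 (95% bootstrap interval over genes -0.196 to -0.121), which argues against mixing as the whole cause if unlogged values follow RNA amount. Bootstrap intervals in this paragraph resample genes, which are not independent replicates, and hold no variation between arrays or mice. A narrower spread of that array's values before RMA cannot be judged here, because RMA had already normalized by quantiles. RMA had left its quartiles at 4.485 and 7.794, against 4.308 to 4.421 and 7.815 to 7.932 on the other arrays. A further quantile normalization over all rows makes the distributions equal. After it the share was 0.504 (95% bootstrap interval over genes 0.484 to 0.533), hardly moved from 0.507. The small difference in spread left after RMA thus does not account for the share in these genes. A milder injury of that kidney may remain as an explanation, untested because the labels give no measure of injury per mouse.

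Car3, Psca and Upk1b were among the largest decreases, and markers of fat and urothelium were lower in the same AKI arrays. The 10 fat markers other than Car3 had a median of -0.824 (range -1.78 to 0.33, 1 past the test), and the 9 urothelial markers other than Psca, Upk1a and Upk1b one of -0.468 (range -1.40 to -0.04), with Upk2, Upk3a, Upk3b and Snx31 past the test. Within groups the mean of the fat markers tracked Car3 (correlation of deviations 0.890) and that of the urothelial markers tracked Upk1b (0.939), and control replicate 1 and AKI replicate 3 were both highest in their groups for 6 fat and 4 urothelial markers, against 1.1 and 1.0 expected by chance. That expectation holds only for arrays picked in advance and markers that vary independently. Neither applied here, so the counts of ranks are descriptive. Less fat or less pelvic urothelium in the AKI samples could each account for part of these decreases, and neither can be told apart from a response of these genes to injury, because the tracking met the bound of 0.8 set before the test for each, while both medians lay between the bounds of -1 and -0.3. Car3 itself was 10.76, 9.66 and 8.46 on control replicates 1, 2 and 3 and 6.71, 4.87 and 8.16 on AKI replicates 1, 2 and 3. Upk1b ordered these arrays alike, at 8.79, 7.74 and 6.77 in control and 5.10, 4.54 and 6.17 in AKI. The tracking thus cannot tell fat from urothelium, or either from another pattern shared by the arrays.

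Cyp4a12b and Cyp4a12a, genes more abundant in male than in female kidney, rose in these female mice. Male kidneys among the AKI arrays are argued against by 4 Y-linked genes, of which none lay more than 0.119 above the highest control array. Cross-hybridization from 4 other Cyp4a genes is argued against by their largest difference of -0.415. Over 7 other male-biased genes the median was -0.255 (range -1.50 to 0.06), so they did not rise as a set. This cannot decide on a general shift towards male-biased expression, because a fall with the injury could mask it. The proximal tubule list, which holds Slco1a1 of these genes, fell by a median of -0.83. Slco1a1 was also dim, with group means of 2.96 in control and 3.02 in AKI. A response of Cyp4a12 genes to the injury, or a masked shift towards male-biased expression, may be the hypotheses left, found and examined on the same data.

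In the 10 splits of the 6 arrays into 3 and 3, 1 gave as many differing genes, the real one with 3241, and the highest of the others gave 0. For gene lists, 4 of the 10 splits gave as many lists past camera as the real 22, and the highest of the others gave 25. A share under 0.05 cannot be reached with 10 splits. Every split but the real one also placed AKI and control arrays together in each group. The difference between AKI and control then widened the spread within groups, which by itself lowers the count of differing genes. Part of that difference also stayed between the groups, so the list counts were not free of it. The splits therefore cannot show what counts would arise without an effect, and no conclusion is drawn from them.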

How the results depend on the processing

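The settings named here were planned, except the counts of list members without each array, added after seeing the data. Counts of differing genes were within 1.5 times the main 3241 under the 3 other normalizations, both filters, cluster averaging, the full set of rows, both eBayes variants and the authors' deposited table, and calls shared with the main comparison had no opposite sign in any setting but the full set of rows, where this was not counted. The authors' table is no independent check. Over all rows it and the limma fit here called the same 3485 rows and ranked the p-values alike. Calls lost in it reflect adjustment over all rows in place of the genes tested. Array weights gave 10716 (5659 higher, 5057 lower), but gave AKI replicate 2 a weight of 53.8 against 0.164 to 0.894 for the other arrays and did not reach the numerical tolerance. A threshold of 0.01 gave 739 (379 higher, 360 lower, 310 at least 2-fold) and treat 39 (27 higher, 12 lower, all 39 at least 2-fold), both stricter by construction. With the replicate number as a block, 1994 genes differed (884 higher, 1110 lower). Deviations of same-numbered arrays correlated at -0.303, 0.0716 and -0.275, against -0.0688 to 0.342 for arrays of unlike number. No pairing by number was seen, but with 3 arrays per group it is not excluded. Leaving out single arrays, with fewer arrays by construction, gave 590 to 5364 differing genes, 318 to 2938 higher, 272 to 2426 lower and 245 to 888 at least 2-fold. The lowest counts came without AKI replicate 2, the highest without AKI replicate 1. No list was tested on the full set of rows, at the 0.01 threshold or with treat. In the other settings 20 to 25 lists passed, except with an estimated correlation, where 0 did. That setting tests the same shift and leaves the medians as they were, but takes the correlation between genes of a list from the data (-0.0208 to 0.903) and uses 4 degrees of freedom in place of 22059; their shares in the loss were not separated.

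Lists that lost the call with an estimated correlation had medians of 1.39 (tubular injury), -0.83 (proximal tubule), -0.80 (loop and distal tubule), -0.73 (collecting duct), -0.28 (endothelial), 0.54 (matrix), 0.72 (monocyte and macrophage), 0.72 (chemokines), 0.60 (NF-kB), 0.39 (interferon), 0.36 (complement), -0.45 (fatty acid oxidation), -0.37 (respiratory chain), -1.08 (gluconeogenesis), 0.40 (NRF2), 0.41 (cell death), 0.37 (p53), 0.95 (cell cycle), 0.35 (unfolded protein), 0.64 (immediate early), 0.52 (ribosome biogenesis) and -0.38 (transcription factors). Among genes at or above the median level, NRF2 (0.40) and p53 targets (0.46) lost the call; fry, which tests a list against no change and not against other genes, did not call these (0.40 and 0.37) and called folate (-0.091) and ferroptosis genes (0.13). Fat and adrenal markers were called with array weights (-0.15). Glycolysis turned sign under median centring (-0.0086), among genes at or above the median (-0.052) and with cluster averaging (-0.0033), and T and NK markers with array weights (-0.016). The cause was not tested for these. Without single arrays the medians ranged as follows: podocyte markers -0.15 to 0.014, neutrophil markers -0.015 to 0.062, T and NK cell markers -0.018 to 0.093, perirenal fat and adrenal markers -0.19 to -0.075, erythroid and blood markers -1.09 to -0.38, glycolysis genes -0.046 to 0.026, NRF2 target genes 0.30 to 0.51, p53 target genes 0.26 to 0.45, klotho, vitamin D and phosphate axis genes -0.75 to -0.49. Named genes were followed in every setting but the stricter thresholds and the full set of rows, and kept their direction; of 127, 69 lost the call without AKI replicate 2, 46, 43 and 43 without control replicates 1, 2 and 3, 2 without AKI replicate 1 (Car3 and Ifi44), 16 without AKI replicate 3, 14 with the replicate block, 6 in the authors' deposited table and 3 or fewer in the others. The filters removed 2 and 18 of them. No depth applies to arrays, and signal over background is unknown without detection calls.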

Other observations

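The scan of gene families by symbol root was a test chosen only after the report's results were seen. A root is the part of a symbol before its first digit, so it can also hold genes of another kind. Of 271 roots with at least 10 genes, 35 passed camera (16 up, 19 down), and none did with an estimated correlation, where the lowest adjusted p was 0.833; limma called members of each named below.

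Some genes with the symbol roots of ribosomal proteins (Rpl and Rps) rose by small amounts. Of 65 genes with the root Rpl, 17 rose and 0 fell (median 0.24, camera adjusted p = 1.52e-08). Of 50 with the root Rps, 20 rose and 1 fell (median 0.30, camera adjusted p = 2.30e-07). With an estimated correlation the camera adjusted p was 0.833 for both. Which of these genes encode ribosomal proteins was not checked. Ribosomal protein genes share sequence with pseudogenes, so their values are uncertain. The root Mcm, which holds replication helicase genes among others, had 7 of 10 risen (median 0.95). The root of nuclear pore genes (Nup) had 4 of 21 risen (median 0.33) and that of proteasome core subunits (Psmb) 3 of 11 (median 0.29). Aquaporin genes had 7 of 11 fallen (median -0.91), peroxin genes (Pex) 6 of 17 (median -0.20), acyl-CoA thioesterases (Acot) 7 of 13 with 1 risen (median -0.60), and solute carriers (Slc) 97 of 376 with 20 risen (median -0.11). The sign of each of these medians held under median centring, quantile and cyclic loess normalization.

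Several further genes, chosen after their values were seen, changed by more than 2 log2 units. Slc34a2, a phosphate transporter better known from the lung, rose (2.65 ± 0.25, adjusted p = 0.00355), as did Aldh1a2, an enzyme of retinoic acid synthesis (2.57 ± 0.16, adjusted p = 0.00152), and Steap1, a metalloreductase family member (2.53 ± 0.41, adjusted p = 0.00949). Dcdc2a (2.41 ± 0.27, adjusted p = 0.00423), Akr1b8 (2.21 ± 0.47, adjusted p = 0.0208) and Sprr2g (2.28 ± 0.26, adjusted p = 0.00458) rose too. Hdc, which makes histamine, fell (-2.32 ± 0.16, adjusted p = 0.00214), as did the peptide hormone gene Cck (-2.36 ± 0.35, adjusted p = 0.00777) and the thyroxine deiodinase gene Dio1 (-2.35 ± 0.28, adjusted p = 0.00478). These adjusted p-values are from limma with n = 3 arrays per group. Akr1b8 lost the call in 4 of the 6 fits with 1 array left out and Steap1 in 1.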
